A study of Mus musculus with 88 samples.

How the data were processed

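Bulk RNA sequencing libraries of 9 tissues from 10 male mice were analysed, 5 of them Cdh15 knockouts (KO) and 5 wild type (WT) of the same strain. The mouse was the replicate, with its identifier taken from the labels. All 88 libraries were placed in 18 groups of tissue and genotype from the labels alone. WT kidney 3793543 and WT spleen 3805657 were not analysed here, which left 4 WT mice in those tissues. Per the labels, polyadenylated RNA was made into stranded libraries and sequenced, and all libraries carry one run code, so no batch could be modelled. Whether the counting used the strand, and which aligner and counting tool were used, is not given in the sources used here.

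The deposited count table holds expected counts per gene on mm10, which the authors made from the aligned reads. Of its values 85.54% were whole numbers and 8145 genes had a fraction of a read in at least 1 library, and the expected counts were rounded to whole numbers before the fits. The deposited RPKM table holds the same counts divided by exon length and library total: over genes with at least 200 counts the median ratio of the deposited RPKM to the value recomputed from the counts was within 0.002 of 1 in all 88 libraries, and RPKM was not used in a test. The table has 24453 genes, and 22 further marker sequences, 0 to 0.0323% of the counts of a library, were left out of the fits. Libraries held 8.206 M to 25.14 M counts (M, mega). The limit that 0 reads allow was taken as 3 reads per library. Replicates were checked for duplicated libraries: over 172 pairs of replicates of a group, the smallest chi-square per gene was 5.473 where copies give a value near 0.

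Each tissue was fitted alone with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, robust dispersions, TMM factors). Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15. P-values were adjusted by Benjamini-Hochberg over the tested genes with a threshold of 0.05. The standard error of a log2 fold change was taken from the F statistic. Counts of EDL, gastrocnemius, soleus and tibialis were also summed per mouse, since muscles of 1 mouse are not independent. The 40 muscle libraries were used to test whether the KO-WT difference in soleus differed from the mean difference in the other 3 muscles, and the 20 WT muscle libraries to compare soleus with the other 3. KO and WT are different mice and the genotype tests are unpaired. The ages also form matched sets of KO and WT mice, which the main tests ignore and which were tried as a block. Whether libraries of 1 mouse are linked across muscles was checked. Over 60 pairs of libraries from the same mouse the mean correlation of log2 CPM, after removing group means, was 0.184 (46 above 0.1). The value for other mice of the genotype, -0.0458, largely follows from the first once group means are removed, so it is no separate baseline. The mouse was therefore also tried as a replicate block in the 2 comparisons between muscles.

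The comparisons, the 54 gene lists, the rules that choose the named genes and the alternatives were fixed before the data were examined, at a time when raw counts were assumed. Named genes are Cdh15, 12 fixed myosin, cadherin and muscle regulator genes in the muscles, the largest changes past the threshold at 1 CPM or more (6 each way in the muscle comparisons), up to 5 genes of smallest p where fewer than 5 passed, and the 2 members of smallest p from each called list, where the rule allowed up to 4. Some genes that these rules choose are not reported here. Of 52 lists with at least 5 tested members in some fit, each was tested with camera in limma 3.58.1 on voom log2 CPM at a preset correlation of 0.01, with Cdh15 left out and adjustment over the lists of a fit. Members were counted past the edgeR threshold over all genes and adjusted over the list alone. Fold changes of the 4 muscles were compared by Spearman correlation over 12183 genes. Single quantities were compared by exact permutation of the 10 mice.

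The alternatives were DESeq2 1.42.0 size factors in the edgeR fit, the DESeq2 Wald test, no filter beyond 1 read, age as a covariate, age-matched sets as a block, camera with an estimated correlation, fry, limma with the mouse as a random effect, the mouse as a replicate block, and each mouse left out in turn. Other splits of the mice into 5 and 5 were also fitted, 100 of the 126 (50 for the comparison between muscles), the real one included. The fits were tested on simulated data with 100 genes changed 1.5-fold and 100 changed 2-fold together. All were drawn from genes at a mean of 5 CPM or more. Of genes changed 1.5-fold, 60% (spleen) to 96% (summed muscles) were recovered, 67% in soleus and 82% in EDL. Of genes changed 2-fold, 90% (spleen) to 99% (heart) were recovered, with 5 to 14 wrong calls per comparison. With so many true changes the adjusted threshold is easier to pass, so these shares may overstate recovery where few genes change. A shifted list was recovered in 10 of 10 fits and 2 of 323 unshifted lists were called. The simulated genes were drawn independently, so this does not test the preset correlation. Other splits of the real mice gave a median of 78 list calls over the 10 fits, against 77 for the real one. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.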

Results

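Polyadenylated RNA was sequenced from 9 tissues of 10 male C57BL/6NTac mice, of which 5 carried a knockout of Cdh15 (KO) and 5 were wild type (WT). Cdh15 encodes M-cadherin, a calcium-dependent adhesion protein of muscle precursor cells and muscle fibres. The mice were 65 to 85 days old and had been fasted for 18 h. The tissues were the extensor digitorum longus (EDL), gastrocnemius, soleus and tibialis muscles and the heart, kidney, liver, lung and spleen. Each tissue gave 5 KO and 5 WT libraries, except kidney and spleen with 5 KO and 4 WT libraries, which made 88 libraries. Total counts per library ranged from 8.21 M to 25.1 M with a median of 19.02 M. The highest group mean was that of WT EDL, with 22.4 ± 2.48 M counts, against 20.1 ± 1.55 M in KO EDL (SD, n = 5 each). Spleen was the shallowest tissue, with 11.5 ± 2.71 M in KO (SD, n = 5) and 12.9 ± 4.35 M in WT libraries (SD, n = 4). By its title, the study asked what M-cadherin does in fetal muscle formation and for the adult muscle, and the comparison made here was KO against WT in each adult tissue.

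Cdh15 transcripts were abundant in WT muscle and strongly reduced in KO muscle. The gene (Entrez 12555) lies on chromosome 8 of mm10 from 122848374 to 122867397 on the plus strand, and the deposited annotation gives it 14 exons and 2843 exonic bases. In EDL it stood at 19.2 ± 3.06 CPM (counts scaled to library size) in WT and 2.92 ± 0.37 CPM in KO mice (SD, n = 5 each), and it fell by 2.71 on the log2 scale (SE 0.13, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.33e-07). In gastrocnemius it stood at 17.3 ± 1.19 against 2.29 ± 0.44 CPM and fell by 2.92 (SE 0.12, edgeR adjusted p = 5.18e-09). In soleus the levels were 17.5 ± 3.38 and 2.58 ± 0.81 CPM, so that it fell by 2.77 (SE 0.20, edgeR adjusted p = 0.000161). In tibialis they were 15.03 ± 3.1 and 1.41 ± 0.28 CPM, so that it fell by 3.41 (SE 0.18, edgeR adjusted p = 8.95e-07). The KO level was 15.2% of the WT level in EDL, 13.3% in gastrocnemius, 14.7% in soleus and 9.39% in tibialis. No KO muscle library exceeded 3.93 CPM and no WT muscle library lay under 11.5 CPM. With reads pooled over the 4 muscles of each mouse, Cdh15 was lower in the 5 KO than in the 5 WT mice (difference of -15.2 CPM, exact 2-sided permutation p = 0.00794, the smallest that the 252 relabellings allow). In heart, kidney, liver, lung and spleen each library of either genotype held 0 to 2 Cdh15 reads. These lie under the limit of 3 reads that a count of 0 allows (at most 0.37 CPM in any library), so no fold was computed there. The part of the gene that the KO allele lacks is not given in the sources used here, and the counts per gene do not place the remaining reads on exons.

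**Figure D1:**
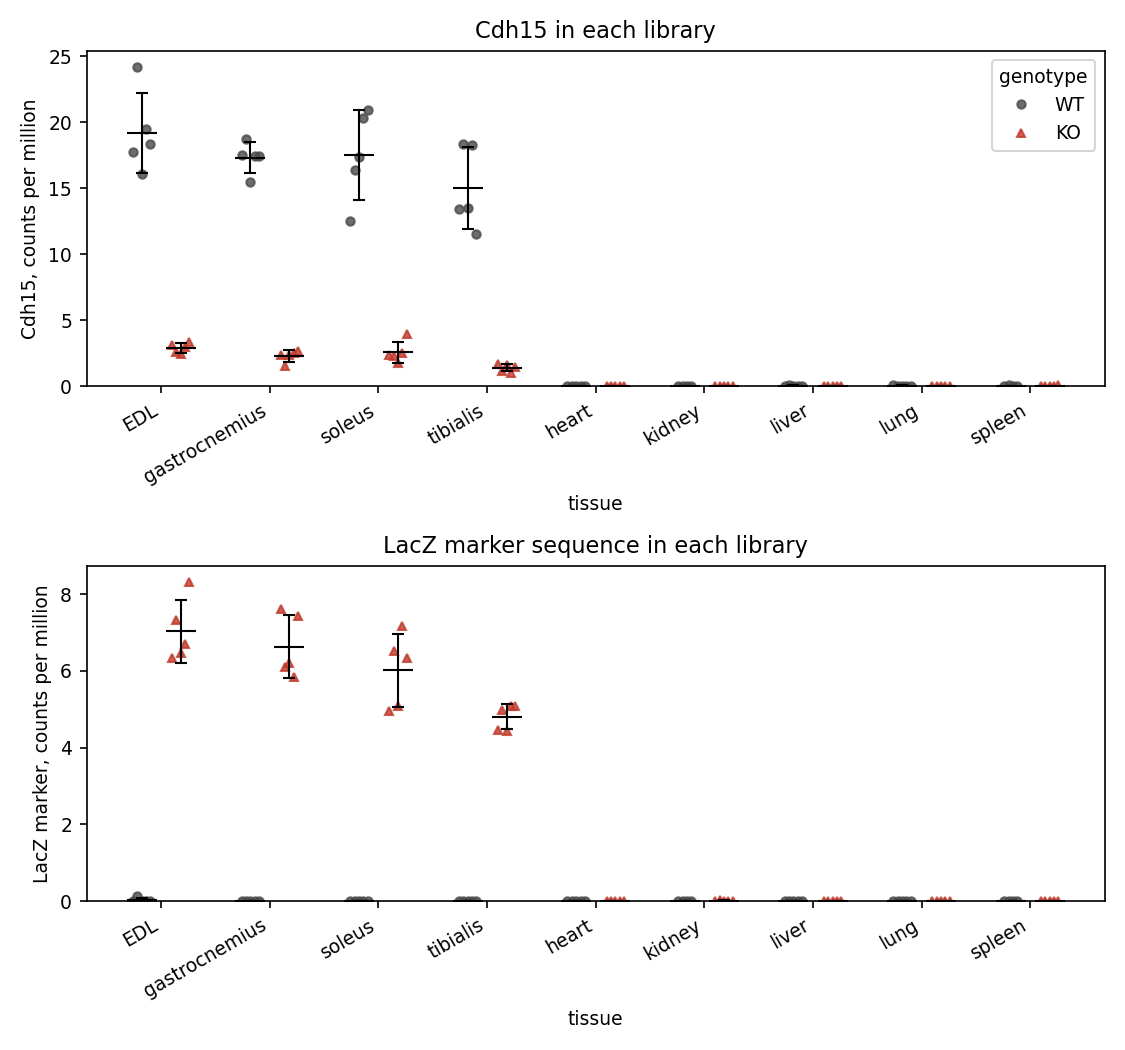
Points show the level of Cdh15 (upper panel) and of the LacZ marker sequence (lower panel) in CPM in each library by tissue, with WT as circles and KO as triangles, and bars give the mean ± SD. Cdh15 lay at 11.5 CPM or more in each WT muscle library and at 3.93 CPM or less in each KO muscle library, and LacZ was read in KO muscle with 2288 reads in total against 3 in WT muscle.

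In the KO EDL, lists of mitochondrial energy production ranked higher and lists of slow fibres and fat cells ranked lower at the preset correlation of camera. Of 28 genes of oxidative phosphorylation, 27 had a positive fold change, with a median log2 fold change of 0.18 (camera adjusted p = 4e-17, adjusted p = 0.543 with an estimated correlation). The respiratory chain subunits Cox5a (0.53, SE 0.13) and Cyc1 (0.36, SE 0.10) led this list. All 19 genes of fatty acid oxidation had a positive value (median 0.15, camera adjusted p = 3.07e-08, adjusted p = 0.607 with an estimated correlation), with Acadl at 0.26 and Hadhb at 0.25. All 13 heat shock genes were positive (median 0.15, camera adjusted p = 3.39e-05, adjusted p = 0.543 with an estimated correlation), led by Hspa1b at 1.42 (SE 0.40), whose reads can be shared with its near-identical neighbour Hspa1a at 0.76. Genes of mechanical stress ranked higher as well (median 0.22, 13 of 15 positive, camera adjusted p = 0.0121, adjusted p = 0.625 with an estimated correlation). Slow-fibre genes ranked lower, with 12 of 15 negative (median -0.30, camera adjusted p = 0.00447, adjusted p = 0.607 with an estimated correlation). Among them the slow troponins Tnnc1 at -1.70 (SE 0.50) and Tnni1 at -1.63 (SE 0.56) stood at 6.35 ± 4.41 and 3.55 ± 2.75 CPM in WT mice (SD, n = 5). Fast-fibre genes also ranked lower (median -0.08, 12 of 14 negative, camera adjusted p = 0.0147, adjusted p = 0.607 with an estimated correlation). The adipocyte list ranked lower with 11 of 12 negative (median -0.59, camera adjusted p = 0.00806, adjusted p = 0.607 with an estimated correlation), including leptin (Lep) at -1.10 and perilipin (Plin1) at -0.97. The lists of nerve sheath (median -0.14, camera adjusted p = 0.00936), interferon response (median -0.17, camera adjusted p = 0.0147) and embryonic or regenerating fibre genes (median -0.11, camera adjusted p = 0.0422) ranked lower too, with adjusted p = 0.689, 0.625 and 0.543 with an estimated correlation. Without KO mouse 3779417 the nerve sheath list turned direction and was not called (adjusted p = 0.762). The 10 list calls in EDL became 4 without WT mouse 3805673 and 6 without KO mouse 3805666.

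Cdh15 was the only one of 12875 genes tested in EDL that passed the edgeR threshold, and 590 genes had an unadjusted p under 0.05 where 644 would be reached by chance. That count was 1092 without WT mouse 3817948 and 390 without WT mouse 3793553. Next by p were the mitochondrial acyl carrier protein Ndufab1 (0.75, SE 0.14, edgeR adjusted p = 0.714), Plac9a, Mrps34, the clock repressor Nr1d1 (-0.38, SE 0.09, edgeR adjusted p = 0.986) and Rnaset2b. Plac9a and Rnaset2b share reads with near-identical copies and are uncertain. DESeq2 called 4 genes, Cdh15, Ndufab1, Plac9a and the myosin gene Myh6, which was named after its values were seen. In the called lists, adjusted over the list alone, 1 gene of oxidative phosphorylation (Cox5a) and 1 gene of the embryonic and regeneration list (the perinatal myosin Myh8, -0.50) passed in EDL, against 0 over all genes (edgeR).

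In gastrocnemius the slow-fibre genes ranked higher in KO mice, the opposite of EDL. All 15 were positive, with a median log2 fold change of 0.36 (camera adjusted p = 1.29e-09, adjusted p = 0.636 with an estimated correlation). Sarcolipin (Sln), an inhibitor of the calcium pump, stood at 0.31 ± 0.11 CPM in WT and 0.79 CPM in KO (log2 fold change 1.32, SE 0.31, edgeR adjusted p = 1), and the regulatory light chain Myl2 lay at 0.49 (SE 0.18). Genes of mechanical stress (median 0.07), fatty acid oxidation (0.05), immediate early genes (0.19) and heat shock genes (0.08) ranked higher, with camera adjusted p of 0.0156, 0.00147, 0.0157 and 0.00944. Nerve sheath genes ranked lower (median -0.32, 12 of 13 negative, limma camera adjusted p = 3.95e-07), with the Schwann cell factor Sox10 at -0.55. Endothelial genes (median -0.13, 15 of 15 negative, limma camera adjusted p = 0.00147) and interferon genes (median -0.21, camera adjusted p = 0.00618) ranked lower too. Each of these 8 lists had an adjusted p = 0.636 with an estimated correlation, and without WT mouse 3805673 5 lists were called. Among the members of these 8 lists, Sln alone passed when adjusted over the list alone. Cdh15 was the only one of 12624 genes past the edgeR threshold, with 246 at an unadjusted p under 0.05. The carbonic anhydrase Car3 followed (-0.26, SE 0.05, edgeR adjusted p = 0.601) and was the second gene of the 2 that DESeq2 called, and Cd24a, Dennd1c and Adarb1 had edgeR adjusted p = 1.

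In tibialis the nerve sheath genes ranked lower in KO mice and fat cell genes ranked higher at the preset correlation of camera. Nerve sheath genes were also called lower in gastrocnemius, but both muscles came from the same mice, so this is not an independent repeat. All 12 nerve sheath genes were negative (median -0.48, camera adjusted p = 4.88e-10, adjusted p = 0.319 with an estimated correlation), with S100b at -0.86 (SE 0.27) and periaxin (Prx) at -0.55 (SE 0.21). All 12 adipocyte genes were positive (median 0.36, camera adjusted p = 0.00153, adjusted p = 0.42 with an estimated correlation), with the lipid droplet gene Cidec at 0.62 (SE 0.26). Fibroblast genes (median 0.10, camera adjusted p = 0.0359) and macrophage genes (median 0.12, camera adjusted p = 0.00331) ranked higher, both with adjusted p = 0.874 with an estimated correlation. Without WT mouse 3793553 the fibroblast list turned direction and was not called (adjusted p = 0.979), and the 7 list calls in tibialis became 4. The calls became 13 without KO mouse 3805666 and 11 without any 1 of WT mice 3805657, 3805673 and 3817948 and KO mouse 3817943. Satellite cell genes (median -0.08, camera adjusted p = 0.0253, adjusted p = 0.319 with an estimated correlation) ranked lower, with Heyl at -0.25 and Fgfr4 at -0.45. Neuromuscular junction genes (median -0.07, camera adjusted p = 0.0344, and 0.0593 with age as a covariate) and smooth muscle and pericyte genes (median -0.13, camera adjusted p = 0.00315) ranked lower with adjusted p = 0.42 with an estimated correlation. The satellite cell regulators Pax7 (0.01, SE 0.17) and Myod1 (-0.43, SE 0.23) did not pass the edgeR test. Cdh15 was the only one of 12348 genes past the threshold by edgeR and by DESeq2, with 219 at an unadjusted p under 0.05 (335 without WT mouse 3817948). Tnnt2 (-1.04, SE 0.27), Bhlhe40, Col20a1, Inpp4a and Fam46b followed, each with edgeR adjusted p = 1.

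In the KO soleus, lists of slow-fibre and oxidative genes ranked higher and lists of fast-fibre and glycolytic genes ranked lower at the preset correlation of camera, while no gene other than Cdh15 passed the edgeR threshold. All 15 slow-fibre genes were positive, with a median log2 fold change of 0.93 (camera adjusted p = 2.66e-10, adjusted p = 0.551 with an estimated correlation). The slow myosin Myh7 stood at 2806 ± 909 CPM in WT and 5234 CPM in KO mice (0.90, SE 0.28), and Sln at 4.35 ± 1.46 and 15.03 CPM (1.80, SE 0.35), both with edgeR adjusted p = 0.238. Of the 19 genes of fatty acid oxidation 18 were positive (median 0.41, camera adjusted p = 9.33e-12, adjusted p = 0.551 with an estimated correlation), among them Cpt2 (0.39) and Acaa2 (0.52). All 28 genes of oxidative phosphorylation were positive (median 0.22, camera adjusted p = 1.7e-10, adjusted p = 0.641 with an estimated correlation), among them Ndufb5 (0.35) and Cox7a1 (0.44). Of 14 fast-fibre genes 13 were negative (median -0.53, camera adjusted p = 1.61e-05, adjusted p = 0.641 with an estimated correlation), with Tnnt3 at -0.40 and Mylpf at -0.51. Of 19 glycolysis and glycogen genes 17 were negative (median -0.39, camera adjusted p = 4.2e-05, adjusted p = 0.641 with an estimated correlation), with the glycogen phosphorylase Pygm at -0.65. Adjusted over the list alone, 13 slow-fibre, 18 fatty acid oxidation and 15 oxidative phosphorylation genes passed the edgeR test, against 0 of each over all genes. The fast myosin Myh4 differed widely between mice: it ranged from 28390 to 69940 CPM in the WT soleus and from 26870 to 40810 CPM in 4 KO libraries, and stood at 84.7 CPM in the soleus library of KO mouse 3805666. Without that library the 5 lists kept their calls. The glycolysis median was then -0.24, the fast-fibre median -0.38 and the slow-fibre median 0.65. With log2 Myh4 as a covariate, chosen after the data were seen, these medians were -0.18, -0.25 and 0.56. In WT EDL it ranged from 66980 to 86350 CPM.

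Other lists ranked apart in the KO soleus. Macrophage genes lay higher in 14 of 14 cases (median 0.55, camera adjusted p = 0.000455, adjusted p = 0.724 with an estimated correlation), with Adgre1 at 0.81 and Mrc1 at 0.60. Lists of other cell types leaned the same way in soleus but were not called by camera: nerve sheath (14 of 14 positive, median 0.30, adjusted p = 0.147), adipocyte (11 of 12, median 0.30, adjusted p = 0.147), endothelial (15 of 15, median 0.14, adjusted p = 0.156) and fibroblast (14 of 15, median 0.12, adjusted p = 0.0976). Genes of mechanical stress (median 0.46, camera adjusted p = 0.0121, adjusted p = 0.732 with an estimated correlation) and of the fasting response (median 0.32, camera adjusted p = 0.00965, adjusted p = 0.641 with an estimated correlation) ranked higher, as did heat shock genes (median 0.12, camera adjusted p = 0.0393, adjusted p = 0.641 with an estimated correlation). Embryonic and regeneration genes ranked higher (median 0.32, camera adjusted p = 0.0357, adjusted p = 0.551 with an estimated correlation). Their members Ncam1 (0.53, SE 0.14), a neural adhesion molecule, and Chrna1 (0.45, SE 0.13), a subunit of the acetylcholine receptor, passed when adjusted over the list alone. Clock genes ranked lower (median -0.25, camera adjusted p = 0.00192, adjusted p = 0.444 with an estimated correlation), and Nr1d1 (-0.37) and Bhlhe41 (-0.58) passed when adjusted over the list alone. Atrophy genes (median -0.15, camera adjusted p = 0.0253, adjusted p = 0.732 with an estimated correlation) and p53 targets (median -0.18, camera adjusted p = 0.0466, adjusted p = 0.641 with an estimated correlation) ranked lower, with the ubiquitin ligase Trim63 at -0.77. The related cadherin Cdh4 stood at 2.90 ± 1.63 CPM in WT and 0.79 CPM in KO mice (-1.87, SE 0.47, edgeR adjusted p = 0.238), while Cdh2 (0.01, SE 0.20), Cdh11 (0.06, SE 0.14) and Cdh13 (0.12, SE 0.08) did not pass either.

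Of 12965 genes tested in soleus, Cdh15 alone passed the edgeR threshold and 2235 had an unadjusted p under 0.05 (1484 without WT mouse 3805673). The genes next by p were Chid1 (0.56, SE 0.08, edgeR adjusted p = 0.133), Trmt2b (0.43), Xdh (0.42), the RNA-binding protein Rbm24 (-0.47, SE 0.09) and Agpat2 (0.59), the last 4 with edgeR adjusted p = 0.238. DESeq2 called 165 genes in soleus, 110 higher and 55 lower. Cdh15 was not among them. The filter on mean counts in DESeq2 may have left it without an adjusted p there.

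**Figure D2:**
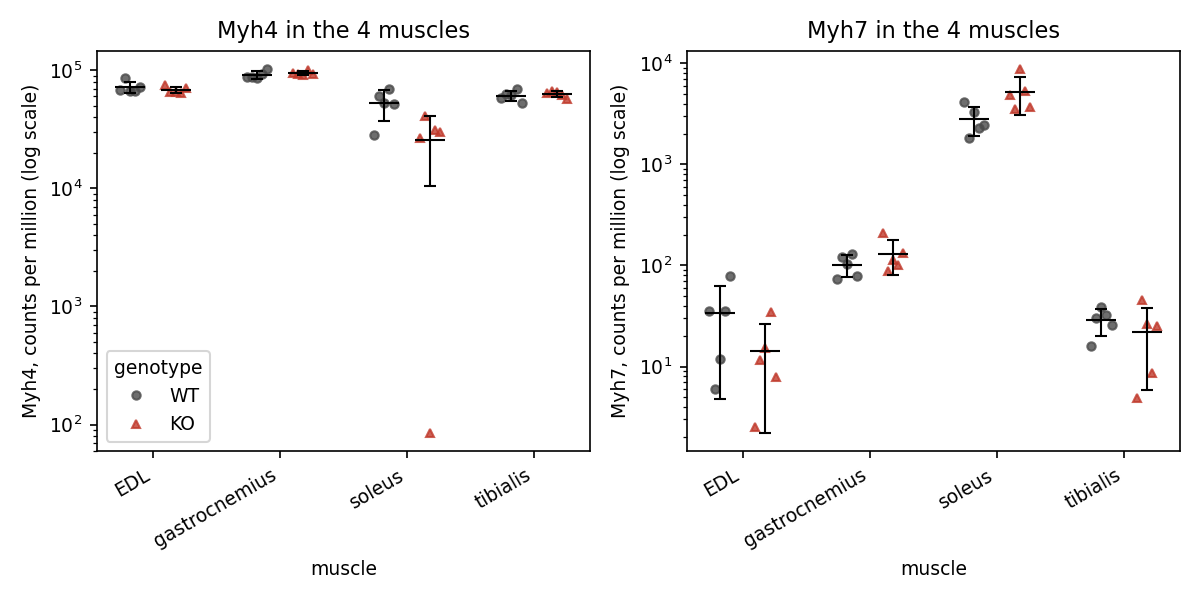
Points show the fast myosin Myh4 (left) and the slow myosin Myh7 (right) in CPM on a log axis in each library of the 4 muscles, with WT as circles and KO as triangles and bars for the mean ± SD computed on the linear scale. One KO soleus library, at 84.7 CPM of Myh4, lies far under the other libraries of all 4 muscles.

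With the counts of the 4 muscles summed per mouse, slow-fibre and mitochondrial genes ranked higher in KO mice at the preset correlation. All 15 slow-fibre genes were positive (median log2 fold change 1.13, camera adjusted p = 4.29e-18), as were 28 of 28 genes of oxidative phosphorylation (median 0.13, camera adjusted p = 8.6e-23) and 19 of 19 of fatty acid oxidation (median 0.25, camera adjusted p = 3.24e-23), each with adjusted p = 0.19 with an estimated correlation. Myh7 lay at 1.15 (SE 0.30), Sln at 1.83 (SE 0.32) and the succinate dehydrogenase subunit Sdhb at 0.24 (SE 0.05). Counts were summed without scaling the muscles to equal depth. Soleus libraries averaged 20.24 M counts in KO and 18.36 M in WT mice, while EDL, gastrocnemius and tibialis were each deeper in WT mice. Soleus thus made up more of the KO sum, which by itself raises genes highest in soleus. How much of the summed difference this explains was not tested. Fast-fibre genes ranked lower (median -0.17, camera adjusted p = 1.56e-07, adjusted p = 0.46 with an estimated correlation), as did glycolysis genes (median -0.10, camera adjusted p = 0.000482, adjusted p = 0.881 with an estimated correlation) and dystrophin complex genes (median -0.05, camera adjusted p = 0.0357, adjusted p = 0.46 with an estimated correlation). Clock genes ranked lower (median -0.10, camera adjusted p = 0.00805, adjusted p = 0.19 with an estimated correlation), with Nr1d1 at -0.32 (SE 0.08). Fasting response genes ranked higher (median 0.13, camera adjusted p = 0.00194, adjusted p = 0.46 with an estimated correlation), with Ppara at 0.49, as did heat shock (median 0.08, camera adjusted p = 0.00937, adjusted p = 0.575 with an estimated correlation), fibroblast (median 0.12, camera adjusted p = 0.0113, adjusted p = 0.949 with an estimated correlation) and macrophage genes (median 0.18, camera adjusted p = 0.0359, adjusted p = 0.968 with an estimated correlation). Adjusted over the list alone, 13 slow-fibre, 20 oxidative phosphorylation, 18 fatty acid oxidation, 4 fasting and 1 clock gene passed the edgeR test, against 0 of each over all genes. Cdh15 stood at 17.6 ± 1.78 CPM in WT and 2.35 ± 0.39 CPM in KO mice (SD, n = 5 each) and fell by 2.90 (SE 0.11, edgeR adjusted p = 9.45e-08), the only one of 14537 genes past the threshold. With Cdh15 included, 1144 genes had an unadjusted p under 0.05, and DESeq2 called 100 genes, 92 higher and 8 lower. The unadjusted count was 1740 without WT mouse 3817948. It was 296 when soleus was left out of the sum, an alternative chosen after the data were seen, so the count of 1144 (727 by chance) rested on soleus. Prune2 (0.49), Rnaset2b, Fam126b and Sln were among the next by p, with edgeR adjusted p = 0.311. Pax7 (-0.10, SE 0.14), Myh3 (0.32, SE 0.16) and Myh8 (-0.12, SE 0.10) did not pass.

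Within WT mice the largest positive differences of the soleus from the mean of the other 3 muscles included slow-fibre proteins. The slow troponin Tnni1 was 5.84 log2 units higher (SE 0.24, edgeR adjusted p = 1.03e-11), at 247 ± 48.4 CPM against 5.02 ± 0.99 CPM (SD, n = 5 mice each). Myh7 (5.80, SE 0.36), Tnnt1 (5.74, SE 0.27) and Tnnc1 (5.74, SE 0.25) were higher to the same extent, and the fast oxidative myosin Myh2 was 2.65 higher (SE 0.30, edgeR adjusted p = 5.72e-06). Tecrl and Mhrt, at 4.59 and 4.41 CPM in soleus, stood at 0.03 and 0.08 CPM in the other muscles, so their folds (7.49 and 5.78) rest on very few reads there. Myh4 was lower in soleus, with a log2 difference of -0.61 (SE 0.13, edgeR adjusted p = 0.00192), at 49260 ± 14200 against 76570 ± 3400 CPM. It thus kept 64.3% of its mean level in the other 3 muscles. How much of the Myh4 came from other muscle taken with the soleus was not measured. The differences given here may therefore not be those of soleus alone. Among genes at 1 CPM or more in soleus or the other muscles, those with the largest negative differences were the protease Mmp3 (-1.78), the Wnt antagonists Sfrp4 (-1.76) and Sfrp2 (-1.69), the stretch-responsive gene Ankrd1 (-1.69), Cyp4f39 (-1.60) and Nr4a3 (-1.57). In all, 2698 of 13172 genes passed, 1684 higher and 1014 lower in soleus. Without WT mouse 3793543, whose soleus had the lowest Myh4, 1498 genes passed.

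The genotype difference in soleus was compared with the mean difference in the other 3 muscles. Ncam1 had a log2 fold change of 0.53 in soleus and -0.10 in the other muscles, and the transcription factor Mafa -1.62 and 0.05, so that their differences were 0.64 (SE 0.14) and -1.67 (SE 0.31). Rsph3b (difference 0.58), A930016O22Rik (-0.60) and Fam132a (-0.62) followed, and all 5 had edgeR adjusted p = 0.0621. For Cdh4 the difference was -1.45 (SE 0.43, edgeR adjusted p = 0.102) and for Myh7 1.32 (SE 0.60, edgeR adjusted p = 0.259). No gene of 13534 passed with edgeR, 2225 had an unadjusted p under 0.05, and DESeq2 called 332 genes. With the mouse as a replicate block, edgeR called 591 genes, 183 with a higher and 408 with a lower difference in soleus, and the 5 genes named first had adjusted p = 0.0229 there. Leaving out WT mouse 3793543 gave 384 genes, leaving out KO mouse 3793546 gave 337 and leaving out WT mouse 3805657 gave 1, so the count without a block rested on single mice.

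The fold changes of the 4 muscles were compared over 12183 genes tested in each, Cdh15 left out. The Spearman correlation across genes, which are not independent replicates, was 0.19 between EDL and soleus, 0.15 between gastrocnemius and tibialis, 0.09 between EDL and gastrocnemius, 0.08 between EDL and tibialis, 0.06 between gastrocnemius and soleus and -0.05 between soleus and tibialis. Their mean was 0.0884 (0.212 without WT mouse 3817948, 0.0546 without WT mouse 3805657). Other assignments of the 10 mice to the genotypes, applied jointly to all muscles, gave means with a median of 0.178, and 91 of 100 splits, the real one included, gave a mean at least as large as the real one.

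In the KO heart the list with the smallest camera p was that of atrial genes. The 6 list calls in heart became 1 without KO mouse 3793546 and 1 without WT mouse 3793553. There were 10 without WT mouse 3805657 or KO mouse 3817943. All 9 genes of the atrial list were positive, with a median log2 fold change of 0.54 (camera adjusted p = 3.39e-12, adjusted p = 0.616 with an estimated correlation), and the atrial natriuretic peptide gene Nppa stood at 360 ± 67.9 CPM in WT and 541 CPM in KO mice (0.59, SE 0.20). Fast-fibre (median 0.21, camera adjusted p = 0.0187), adipocyte (median 0.18, camera adjusted p = 0.0372) and cardiac stress genes (median 0.18, camera adjusted p = 0.0391) ranked higher, all with adjusted p = 0.616 with an estimated correlation. Nppa is also in the cardiac stress list and had the smallest p there, so the atrial and cardiac stress calls are not independent. The fast-fibre genes Myl1 (0.28) and Atp2a1 (0.71) passed when adjusted over the list alone. Genes of oxidative phosphorylation (median -0.04, 28 of 28 negative, camera adjusted p = 0.000245, adjusted p = 0.82 with an estimated correlation) and macrophages (median -0.13, camera adjusted p = 0.00763, adjusted p = 0.745 with an estimated correlation) ranked lower. By edgeR and by DESeq2, 0 of 13438 genes passed, and 421 had an unadjusted p under 0.05 in edgeR. Jmjd7, the amidating enzyme Pam (0.30, SE 0.07), Slc15a2, Sds and Lrp2 had the smallest p, with edgeR adjusted p = 0.999.

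In the kidney, fat cell genes ranked higher in KO mice. The same list was called lower in EDL and higher in tibialis, heart and lung. Whether these transcripts came from fat taken with the kidney was not tested. All 12 adipocyte genes were positive with a median of 0.53 (camera adjusted p = 1.56e-12, adjusted p = 0.074 with an estimated correlation), and 7 of these adipocyte genes, Adipoq, Plin1, Plin4, Cidec, Cfd, Acvr1c and Lipe, passed the edgeR test when adjusted over the list alone, against 0 over all genes. Cidec stood at 12.2 ± 1.47 CPM in WT (SD, n = 4) and 19.3 CPM in KO mice (0.66, SE 0.11, edgeR adjusted p = 0.25), and the complement protease Cfd at 30.4 ± 5 and 48.3 CPM (0.67, SE 0.14). The stress-response gene Sesn2 had the smallest p, at 40 ± 3.45 and 54.5 CPM (0.45, SE 0.07, edgeR adjusted p = 0.231), and its list of the integrated stress response ranked higher (median 0.15, camera adjusted p = 0.000512, adjusted p = 0.407 with an estimated correlation). Sesn2 in that list and Cidec in the fasting list passed when adjusted over the list alone. The fasting list, which holds Cidec too (median 0.11, camera adjusted p = 0.000498, adjusted p = 0.737 with an estimated correlation), and adherens junction genes (median 0.04, camera adjusted p = 0.0453, adjusted p = 0.371 with an estimated correlation) ranked higher. Lymphocyte genes (median -0.36, 10 of 10 negative, camera adjusted p = 0.000498, adjusted p = 0.457 with an estimated correlation) and oxidative phosphorylation genes (median -0.05, camera adjusted p = 0.000374, adjusted p = 0.479 with an estimated correlation) ranked lower. The 6 list calls in kidney became 10 without WT mouse 3805657 or KO mouse 3805676. With edgeR 0 of 14274 genes passed and 478 had an unadjusted p under 0.05 (774 without WT mouse 3805657), and DESeq2 called 4 genes, all higher in KO mice: Sesn2, Cidec, Cfd and Plin4. Fancd2 and Adipoq were next in the edgeR test.

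In liver, lung and spleen camera called 4, 8 and 4 lists at the preset correlation. Other splits of the mice gave medians of 6, 7 and 5 calls, so no shift by genotype is shown. In liver, sterol synthesis genes ranked higher in KO mice (median 0.19, 18 of 19 positive, limma camera adjusted p = 0.000126), with Mvk at 0.30, as did immediate early genes (median 0.19, camera adjusted p = 0.00118) with Junb at 0.81 and genes of the male liver pattern (median 0.17, camera adjusted p = 0.0346), while oxidative phosphorylation genes ranked lower (median -0.03, camera adjusted p = 0.0183). All 4 had adjusted p = 0.995 with an estimated correlation. In liver 0 lists were called by camera without KO mouse 3779417 and 2 without WT mouse 3793553. In lung, fasting (median 0.12, camera adjusted p = 0.00296) and adipocyte genes (median 0.13, camera adjusted p = 0.000998) ranked higher and lymphocyte (median -0.18, camera adjusted p = 0.000775), heat shock (median -0.11, camera adjusted p = 0.00202), oxidative phosphorylation (median -0.04, camera adjusted p = 0.000998) and alveolar type 1 genes (median -0.07, camera adjusted p = 0.0162) ranked lower, each with adjusted p = 0.538 with an estimated correlation. Endothelial genes ranked higher there (median 0.09, camera adjusted p = 0.0292, adjusted p = 0.873 with an estimated correlation) and sterol synthesis genes lower (median -0.06, camera adjusted p = 0.0114, adjusted p = 0.78 with an estimated correlation). The 8 calls in lung became 3 without WT mouse 3817948 and 5 without KO mouse 3805676. In spleen, fibroblast genes ranked higher (median 0.20, 13 of 15 positive, camera adjusted p = 1.14e-07, adjusted p = 0.0825 with an estimated correlation), with Pi16 at 0.59, and so did neutrophil (median 0.32, camera adjusted p = 0.0025, adjusted p = 0.538 with an estimated correlation) and macrophage genes (median 0.09, camera adjusted p = 0.0226, adjusted p = 0.516 with an estimated correlation). All 14 cell cycle genes were negative in spleen (median -0.17, camera adjusted p = 2.39e-07, adjusted p = 0.516 with an estimated correlation), with Aurka at -0.29 and Top2a at -0.18. The 4 calls in spleen became 11 without WT mouse 3805673, 9 without KO mouse 3779417 and 7 without KO mouse 3805666 or 3805676. By edgeR and by DESeq2 0 genes passed in liver, lung or spleen. In edgeR 194 of 12357, 313 of 15172 and 118 of 13952 had an unadjusted p under 0.05, where chance gives 618, 759 and 698. Without KO mouse 3805676 this count was 386 in liver and 781 in lung, and in spleen it was 442 without KO mouse 3817943 and 280 without WT mouse 3805673. The smallest p belonged to Amn1 in liver (-0.59, SE 0.14), BC094916 (1.11, SE 0.26) in lung, where the basal cell keratins Krt14 (1.72, SE 0.41) and Krt5 (1.20, SE 0.30) were also among the first 5, and the clotting factor F13a1 in spleen (0.72, SE 0.16), each with edgeR adjusted p = 1. Spleen libraries of KO mouse 3817943 and WT mouse 3805673 lay apart from the other 7, and without them 0 genes passed, 640 had an unadjusted p under 0.05 in edgeR and 8 lists were called by camera.

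Over the 10 fits, camera with the preset correlation called 77 of 327 list tests, 44 higher and 33 lower in KO mice, and 0 of these remained with an estimated correlation or in the fry test, whose smallest adjusted p was 0.0582. The lists of collagen and matrix, denervation, lipogenesis, growth signalling, tendon and cartilage, plasma cell, erythroid and the genes next to Cdh15 on chromosome 8 were among the 19 lists called in no fit. The other 11 were acute phase, bile acid, xenobiotic and female pattern genes in liver, proximal tubule, distal nephron, podocyte and injury genes in kidney, airway and alveolar type 2 genes in lung, and red pulp and stroma genes in spleen. The keratinocyte and exocrine pancreas lists had too few expressed members to be tested in any fit.

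**Figure D3:**
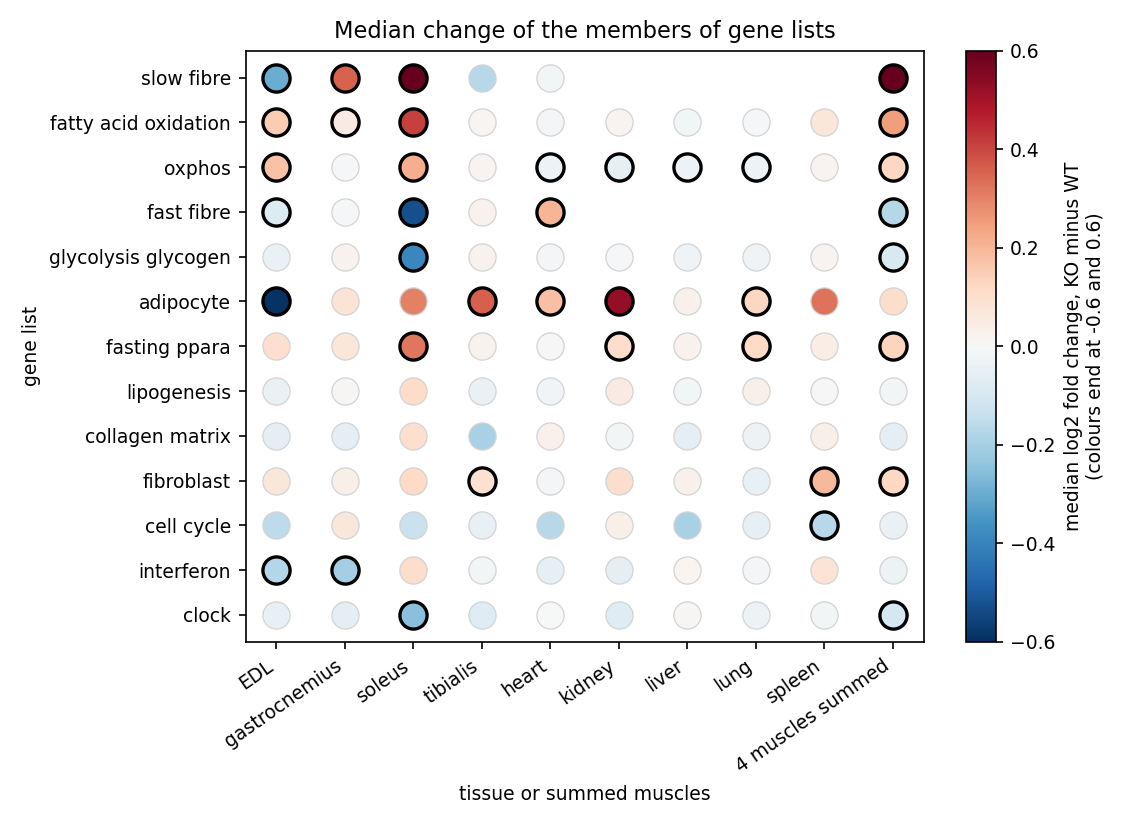
Each point is the median log2 fold change (KO minus WT, colour) of the members of 1 gene list (vertical axis) in 1 tissue or in the 4 muscles summed (horizontal axis), and a black outline marks lists with a camera adjusted p under 0.05 at the preset correlation. The slow-fibre medians of soleus and of the summed muscles, 0.93 and 1.13, lie beyond the end of the colour scale and are drawn in its end colour, and none of the outlined lists passed with an estimated correlation.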

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

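The tests of the Cdh15 reads left in KO muscle and of the spleen libraries were chosen only after the result was seen. So was the choice to count other splits for the blocked comparison between muscles, for the soleus and summed counts at an unadjusted p, and for the soleus lists, whose real counts were known while the counts of their splits were not.

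Other splits of the mice were used to ask whether chance can be excluded. For the count of 1 gene in tibialis, 4 of 100 splits gave as many, the real one included (highest other 3). Tibialis was the lowest of 10 genotype fits, with no correction for their number, so chance is not excluded there. Nor can it be in EDL (6 of 100, real 1, highest other 6), gastrocnemius (11 of 100, real 1, highest other 52), soleus (7 of 100, real 1, highest other 82) or the summed muscles (7 of 100, real 1, highest other 7). In each of these fits the single gene was Cdh15, whose own exact test is in the report. With 0 genes past the edgeR threshold in heart, kidney, liver, lung and spleen, 100 of 100 splits gave as many, as any split must, so these counts say nothing about chance (highest others 78, 54, 29, 1028 and 2). Single splits called far more genes than the real one, 1028 in lung, 82 in soleus and 52 in gastrocnemius, while 90, 93 and 89 of the other splits called 0 genes (edgeR). Such splits point to a structure of the samples, which was not tested. For WT soleus against the other muscles chance can be excluded (1 of 100, real 2698, highest other 1397). For the mean correlation between muscles it cannot (91 of 100, real 0.0884, highest other 0.3513). Nor can it for the list calls over the 10 fits (53 of 100, real 77, highest other 105) or in soleus alone (19 of 100, real 13, highest other 18). At an unadjusted p under 0.05, 2 of 100 splits gave as many genes in soleus (real 2235, highest other 2289), but soleus was the most extreme of 10 genotype fits and was picked for its count, so chance is not excluded there. For the summed muscles it cannot be either (17 of 100, real 1144, highest other 2577).

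The KO-WT difference in soleus differed from that in the other 3 muscles for 591 genes with the mouse as a replicate block, a difference between groups, and for 0 genes in edgeR without it (2225 at an unadjusted p under 0.05, 332 by DESeq2). Of 50 splits, 3 gave as many as 591 with the block, the real one included (highest other 635), so chance cannot be excluded, and without the block 50 of 50 gave as many as 0 (highest other 68).

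In KO soleus the slow-fibre, fatty acid oxidation and oxidative phosphorylation lists ranked higher and the fast-fibre and glycolysis lists lower. The tables argue against 1 library as the whole cause, since 5 of 5 lists kept their direction and call at the preset correlation without KO soleus 3805666, the library almost without Myh4, although the medians shrank (slow fibre 0.93 to 0.65, glycolysis -0.39 to -0.24). A different share of other fast muscle in the dissected soleus may account for the pattern in part or whole. WT soleus was taken as a mix of a soleus without any Myh4 and the mean of WT EDL, gastrocnemius and tibialis. The share of that mean, set by Myh4, was 64.3% in WT and 31.7% in KO soleus. The prediction for KO soleus was WT soleus with the share lowered to the KO value. The KO share came from the Myh4 of KO soleus itself, which a change of fibre types could also lower. A ratio near 1 therefore does not show that dissection is the cause. The predicted over the observed median of the 3 rising lists was 0.973 (0.836 without WT mouse 3805673 to 1.11 without WT mouse 3793543). For the 2 falling lists without Myh4 the predicted median was -0.549 against -0.444 observed. Across genes the predicted and observed changes had a Spearman correlation of 0.529. With log2 Myh4 as a covariate, which is no share and on whose log scale the library at 84.7 CPM lies far from the others, 5 of 5 lists also kept their call (slow fibre 0.93 to 0.56, fast fibre -0.53 to -0.25), which leaves open how much of the pattern a share explains. A change of fibre types in KO mice would move the same genes, was not tested and stays open.

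Cdh15 reads remained in KO muscle at 13.3% of the WT level. Reads passed between libraries are argued against, since LacZ in WT muscle was 0.114% of its level in KO muscle and Cdh15 in the 48 non-muscle libraries 0.068% of its level in WT muscle. Reads shared with a near-identical gene cannot be told apart from reads of Cdh15: all 20 KO muscle libraries had a whole-number Cdh15 count, but so had whichever of Rpl26 and Gm15772 held the reads of that pair in a spleen library, so the test, first taken to exclude sharing, was relabelled after its value was known. A transcript from the part of the gene that the allele keeps stays open and was not tested, since counts per gene do not show exons.

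KO spleen 3817943 and WT spleen 3805673 lay apart from the other 7 spleen libraries on the first principal component, which held 44.4% of the variance. Rpl26 stood at 771 CPM in these 2 libraries and 0 in the other 7 and Gm15772 at 0 and 891 CPM, so reads were assigned differently between near-identical genes, but this is argued against as the whole cause: on 9595 genes with whole counts in each spleen library, which leave out this pair, the gap was still 6.23 times the range of the other 7. Fat or pancreas carried into the spleen cannot be told apart from other causes: the median log2 difference of the adipocyte list was 0.96, its 6 tested members ranged from -0.32 to 3.61, and the exocrine pancreas list had 0 tested members. The bound of 1 for this test was first set to exclude the explanation below it and was changed, after 0.96 was seen, to require the upper quartile (1.86) below 1 as well. Mitochondrial transcripts were higher in the 2 libraries (ND4 14880 against 3907 CPM, ND5 9985 against 2600, CYTB 13500 against 4064), which leaves RNA or tissue quality open as well, and neither that nor a biological explanation was tested.

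Samples far from the others of their group were found in 13 of 216 groups tested, where chance gives 10.8. Chance flags about 1 in 20 groups. WT lung 3805657 had 8.31 M counts (others 18.2 to 20.8). Of WT mouse 3793553, EDL had Myh4 at 86350 CPM (others 66980 to 71610) and Cdh4 at 2.46 (1.09 to 1.37), and gastrocnemius had the perinatal myosin Myh8 at 57.3 (20.6 to 30.01). Of KO mouse 3779417, soleus had the embryonic myosin Myh3 at 69.03 (21.3 to 25.9), gastrocnemius Cdh13 at 40.96 (44.25 to 45.4) and liver Zfp36l2 at 53.3 (34.6 to 39.04). Of KO mouse 3793546, gastrocnemius had Cdh15 at 1.55 (2.35 to 2.66) and spleen F13a1 at 20.3 (12.8 to 14.9). Of WT mouse 3793543, spleen had F13a1 at 7.20 (9.95 to 9.97) and Ada at 15.9 (12.8 to 13.3), and tibialis had Inpp4a at 23.5 (20.8 to 21.2). KO EDL 3817943 had Ndufab1 at 72.6 (51.7 to 55.1).

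A signal in sequences outside the comparisons came from marker rows of the count table, as LacZ had 2288 reads in the 20 KO muscle libraries and SV40 150, against 3 and 0 in the 20 WT muscle libraries. Per mouse, LacZ was 6.23 CPM and SV40 0.41 CPM higher in KO muscle (both exact permutation p = 0.00794, 5 against 5 mice). The 3 WT reads of LacZ were all in WT EDL 3793553, and KO non-muscle libraries held 1.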

How the results depend on the processing

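Added only after the data were seen were Myh4 as a covariate in soleus (1 gene, 1002 at an unadjusted p under 0.05), spleen without 2 libraries (edgeR 0, 640 unadjusted) and the summed muscles without soleus (1 gene, 296 unadjusted).

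Of 238 values of 23 named results past the threshold, 223 kept direction and side and 15 fell short of it. Of 4158 values of 276 named results not past it, 60 passed and 50 moved, and 29 of the 276 results changed sign in at least 1 setting. Of the 77 list calls, 0 were kept with an estimated correlation and 0 with fry, and 76 with age as a covariate, the exception being neuromuscular junction in tibialis (adjusted p = 0.0593). With 1 mouse left out, 604 of 760 values were kept, 154 fell short and 2 turned: the list schwann_nerve, EDL, without KO mouse 3779417 (adjusted p = 0.762, range 0.000338 to 0.762) and the list fibroblast, tibialis, without WT mouse 3793553 (adjusted p = 0.979, range 1.8e-06 to 0.979).

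With the DESeq2 test the counts were 4 in EDL, 2 in gastrocnemius, 165 in soleus, 4 in kidney, 100 in the summed muscles and 332 for the difference between muscles. Age-matched sets as a block left 1 gene past the threshold in EDL and 1 in gastrocnemius. With no filter 1 gene passed in kidney, and with the mouse as a block 591 passed for the difference between muscles. In WT soleus against the other muscles the block gave 3659 genes and brought Myh1 and Myod1 past the threshold. With 1 mouse left out the counts ranged from 1 to 2 in EDL and gastrocnemius (2 without WT 3805657), soleus (2 without KO 3793546) and the summed muscles (2 without WT 3793543). They ranged from 0 to 384 for the difference between muscles (384 without WT 3793543, 337 without KO 3793546, 1 without WT 3805657) and from 1498 (without WT 3793543) to 2450 for WT soleus. The mean correlation between muscles ranged from 0.0546 (without WT 3805657) to 0.212 (without WT 3817948). The cause was not tested. Spleen had the lowest depth and the lowest recovery of genes changed 1.5-fold in simulated data (60%), but soleus, at a higher depth than tibialis, recovered 67% against 77%, so depth alone does not order the tissues.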

Other observations

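The test of the clock was chosen only after the result was seen. The ratio of the clock repressor Nr1d1 to the clock activator Arntl followed the mouse across tissues: over 36 pairs of tissues the mean Spearman correlation of its log2 value was 0.603 (permutation p = 1e-05, the smallest that 100000 permutations can give). The hypothesis is that the phase of the clock at collection may have differed between mice. The KO-WT difference of the log2 ratio was -0.11 (exact permutation p = 0.611, 5 against 5 mice). Times of collection are not given in the sources used here.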
